A study of Mus musculus with 6 samples.

How the data were processed

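Retinae of mouse embryos at E14.5 were compared between 2 genotypes with 3 libraries each, WT and REN_KO, the latter with a deletion of the Atoh7 remote enhancer. Per the labels, the replicates of each genotype are independent. They do not say from how many embryos each came, so p-values measure the spread between these samples. Each deposited file holds whole-number read counts per gene in 3 columns, for both strands together and for each strand, with 4 tallies of reads not assigned to a gene. Per the submitters' processing notes, reads were trimmed with Trimmomatic and aligned with STAR to the mm10 build. Versions, and the gene annotation used for counting, are not given in the sources used here.

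The column for the strand opposite to the read held 97.3% to 98.7% of the strand-specific reads in each library, above the minimum of 80% set in advance, and was used as the count. Library totals were 34369939, 20510332 and 27327875 gene reads for WT and 31728887, 38448147 and 29704716 for REN_KO. The tallies stayed out of library sizes and tests. Multimapped reads were 14.1%, 25.5% and 11.5% of all reads in WT 1, 2 and 3 and 16.3%, 14.4% and 18.0% in REN_KO 1, 2 and 3, and reads outside genes were 27.6%, 19.7% and 38.1% in WT and 25.5%, 19.6% and 19.7% in REN_KO. Depths count reads, and reads amplified by PCR without molecular identifiers are not independent molecules. Libraries of one genotype differed by far more than sampling noise, with a chi-square per degree of freedom of 32.2 or more, and none was a duplicate.

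Gene positions, transcript lengths and GC content came from GENCODE vM21 on GRCm38, the same assembly as mm10. Of 24411 gene symbols 24005 (98.3%) matched 1 gene, 95.6% by symbol and 2.7% by a synonym. Rprl1 has 2 entries there and was given no position.

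The test was edgeR 4.0.16 (glmQLFit and glmQLFTest) in R 4.3.3 with TMM scaling, filterByExpr (minimum count 10, minimum total count 15), genotype as the sole term and Benjamini-Hochberg adjustment over 14693 genes. The standard error of a log2 fold change is its size divided by the square root of the F statistic. Levels are CPM with TMM-scaled library sizes. Gene lists were tested with camera from limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, two-sided, adjusted over the 24 lists with at least 5 tested members. Camera with an estimated correlation and fry were run beside it. Shares of called genes by position were compared with Fisher's exact test, two-sided. With 3 libraries against 3, a permutation p cannot go below 0.1.

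The groups, tests, alternatives, gene lists and naming rule were fixed before the data were examined. The 12 retinal lists covered ganglion cell transcription factors, ganglion cell markers, axon guidance, progenitors, neurogenic precursors, photoreceptors, amacrine and horizontal cells, the Hedgehog and Notch pathways, cell cycle, p53 and apoptosis, and axial patterning. Another 11 covered ciliary margin, pigment epithelium, lens, erythroid, vascular, mesenchyme, microglia, optic stalk and astroglia, immediate early, hypoxia and sex-linked genes, and 1 covered the neighbours of Atoh7. The lists share some members, the most being 6 between axial patterning and axon guidance and 5 between the neurogenic and Notch lists. The naming rule took Atoh7, up to 8 called genes per direction with the largest change, a mean of at least 5 CPM and no overlap between the groups (symbols of predicted genes left out), from each retinal list up to 3 called members in its main direction and 1 in the other, or the member with the smallest p, from each other list its most abundant member and the one with the smallest p, and from the neighbours any called gene or the one with the smallest p. It gave 40 genes. Further members of the lists that passed adjusted over the list alone are named as examples chosen after their values were seen.

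The deposited files carry a sample index that the labels do not describe. WT 2 and REN_KO 3 have 11 and 12, and the other 4 libraries have 3 to 6. The deviations of WT 2 and REN_KO 3 from their group means correlated at 0.385 across genes, more than any other pair. A batch term for these 2 sets had been set out in advance as an alternative setting. Its values are given beside the main fit because the 2 sets stood apart once the data were seen. The set with indexes 11 and 12 holds 1 library per genotype and gives no test by itself, and the other 4 were also fitted alone. The other settings tried were RLE and library-size scaling, DESeq2 1.42.0, limma voom, no or a stricter low-count filter (5 CPM in 3 libraries), the unstranded column, a replicate block, leaving out each library, leaving out genes of lens, blood, pigment epithelium and mitochondria, and stricter thresholds (adjusted p under 0.01, or at least 1 on the log2 scale).

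The tests were checked on simulated counts drawn from the real means, library sizes and dispersions, batch difference included, for 14475 genes, of which 200 were changed singly and 25 lowered together as a list. For the REN_KO against WT comparison the genotype fit called 4.08%, 50.0%, 76.0% and 91.8% of genes changed 1.5, 2, 4 and 8 fold, and the fit with the batch term called 38.8%, 74.0%, 86.0% and 100%. Calls on unchanged genes were 0 of 111 for the genotype fit and 10 of 174 with the batch term. Genes were drawn independently of each other, so these shares hold for that setting.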

Results

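RNA from mouse retina at E14.5 was profiled by bulk RNA sequencing in 3 wild-type libraries (WT) and in 3 libraries from retinae in which a remote enhancer of Atoh7 had been deleted (REN_KO). Atoh7 encodes the basic helix-loop-helix factor that retinal precursors need in order to become ganglion cells, and the series title names ganglion cell genesis and axon growth as its subject. Reads assigned to genes on the transcribed strand numbered 34369939, 20510332 and 27327875 in WT 1, 2 and 3, and 31728887, 38448147 and 29704716 in REN_KO 1, 2 and 3. Of the 24411 genes counted, 14693 were abundant enough to test. WT 2 and REN_KO 3, whose deposited files carry sample indexes 11 and 12, stood apart from the other 4 libraries with indexes 3 to 6 on the second principal component, which held 28.5% of the variance. Values from a fit with these 2 sets of libraries as a batch term are therefore given beside those of the planned fit on genotype alone.

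Atoh7 (chromosome 10, 63099651 to 63101279 in mm10, plus strand) was lower in each REN_KO library than in every WT library. Its level was 118, 186 and 128 CPM in WT 1, 2 and 3, and 18.5, 18.4 and 35.4 CPM in REN_KO 1, 2 and 3. The mean dropped from 144 ± 36.8 CPM in WT to 24.1 ± 9.78 CPM in REN_KO (SD, n = 3 each), which left 16.8% of the WT level. The log2 fold change was -2.58 ± 0.28 (SE), with an edgeR quasi-likelihood adjusted p of 0.0225, and -2.62 ± 0.12 with the batch term, with an edgeR adjusted p of 6.9e-08. Among the libraries with indexes 3 to 6 the log2 fold change was -2.74, and between REN_KO 3 and WT 2 it was -2.38, a pair with no test of its own. The edgeR adjusted p of the genotype fit rose to 0.106 without WT 3, 0.0771 without REN_KO 1 and 0.136 without REN_KO 2, while the log2 fold change stayed between -2.97 and -2.35.

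Beyond Atoh7, the genes that fell included Gng4, Nell2, Nsg2 and Cdh18, and those that rose included Robo3, Pcdh17 and Pcdh20. Gng4, a gamma subunit of heterotrimeric G proteins, fell from 18.4 ± 5.52 to 1.81 ± 0.96 CPM, and its log2 fold change was -3.33 ± 0.38 (edgeR adjusted p = 0.0250). Nell2, a secreted glycoprotein of neurons, fell from 161 ± 22.2 to 80.4 ± 5.01 CPM, Nsg2, an endosomal protein of neurons, fell by 0.86 on the log2 scale, and Cdh18, a type II cadherin, fell by 1.30. Robo3, a receptor of the Roundabout family that acts in commissural axons, rose from 1.86 ± 0.44 to 16.4 ± 1.5 CPM, with a log2 fold change of 3.14 ± 0.24 (edgeR adjusted p = 0.00155). The protocadherin genes Pcdh17 and Pcdh20 rose by 1.07 ± 0.13 and 1.90 ± 0.26 on the log2 scale. Robo3 passed without any 1 library, with an edgeR adjusted p of at most 0.0174. Of the other 6 genes, all lost their call without WT 3 (edgeR adjusted p 0.168 to 0.196) and without REN_KO 1 (0.0752 to 0.133). All but Pcdh20 lost it without WT 1 (0.0624 to 0.259), all but Gng4 without REN_KO 2 (0.149 to 0.321), and Cdh18 and Nsg2 without REN_KO 3 (0.0583 and 0.0516).

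In the genotype fit 6 genes were higher and 7 were lower in REN_KO at an edgeR adjusted p under 0.05. The others that passed were the imprinted genes Rian, a maternally expressed noncoding RNA that fell by 0.92 on the log2 scale, and Peg3, a paternally expressed zinc finger gene that rose by 0.93. Rprl1 and Rprl2, genes for RNase P RNA-like transcripts, rose by 5.35 ± 0.67 and 5.67 ± 0.75, from 0.474 ± 0.648 and 1.23 ± 1.77 CPM to 21.9 ± 5.08 and 69.0 ± 22.2 CPM. They resemble each other and the abundant Rpph1, so the split of reads among them is uncertain, and without WT 1 their log2 fold changes were 7.45 and 8.24. These 4 genes lost their calls without WT 3 (edgeR adjusted p 0.183 to 0.197), REN_KO 1 (0.0771 to 0.128) or REN_KO 2 (0.136 to 0.321). Rian and Peg3 lost theirs without WT 1 (0.259 for each), as did Rian without REN_KO 3 (0.0611). The predicted gene Gm6537, left out by the naming rule and named after its values were seen, fell by 1.66 and completed the 7. The adjusted p values lay close to the threshold, since 32 genes had an edgeR adjusted p under 0.052, and 2157 genes (14.7%) had an unadjusted p under 0.05.

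With the batch term, edgeR called 479 genes higher and 276 lower, which included all 13 genes of the genotype fit. With indexes 3 to 6 alone, 119 genes were higher and 83 lower. Of the 201 of these that were also tested in all 6 libraries, 194 (96.5%) had the same sign in the pair of WT 2 and REN_KO 3, which took no part in that fit. Over genes at 5 CPM or more, called or not, the log2 fold changes of the 2 sets correlated at 0.546. A trend with transcript length, described below, ran the same way in both sets (rank correlations 0.371 and 0.369). Agreement in sign therefore does not separate genotype from that trend. Leaving out WT 1, 2 or 3 changed the genotype fit's counts of higher and lower genes to 5 and 2, 12 and 24, or 1 and 0, and leaving out REN_KO 1, 2 or 3 changed them to 1 and 3, 1 and 1, or 13 and 9. The batch-term counts became 67 and 62 without WT 1, 294 and 257 without WT 3, 269 and 226 without REN_KO 1, and 11 and 13 without REN_KO 2. Without WT 2 or REN_KO 3 their set holds 1 library, so no batch term was fitted. The 119 and 83 genes of indexes 3 to 6 alone, fitted on genotype, stand for both cases.

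**Figure D1:**
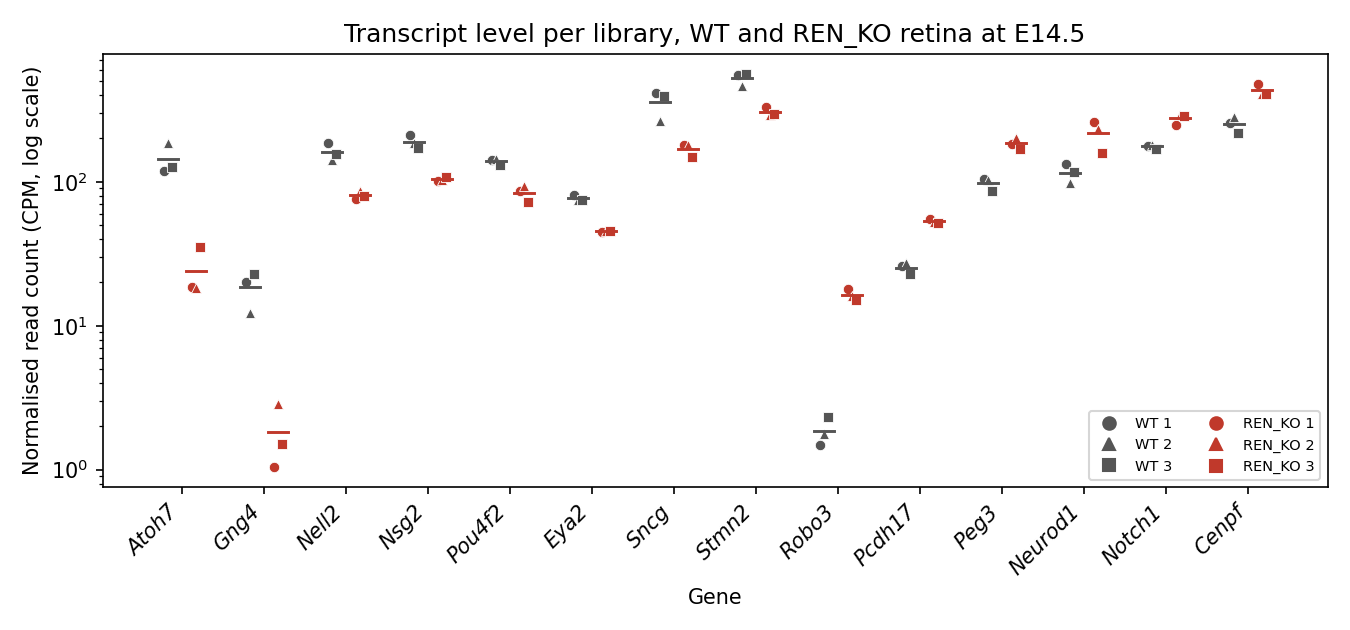
Normalised read counts (CPM, log axis) of 14 genes in each library, with grey symbols for WT, red symbols for REN_KO, a symbol shape for each replicate number and a line at each group mean. Atoh7 fell from a mean of 144 to 24.1 CPM while Robo3 rose from 1.86 to 16.4 CPM.

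Most tested members of the 2 ganglion cell lists had a negative log2 fold change in REN_KO, and list members below that the naming rule did not choose were picked after their values were seen. Pou4f2, the POU-domain factor that acts downstream of Atoh7 in ganglion cell differentiation, had 139 ± 6.69 CPM in WT and 84.2 ± 10.8 CPM in REN_KO (log2 fold change -0.72 ± 0.13). Isl1, its LIM-homeodomain partner, went from 228 ± 51.0 to 144 ± 27.3 CPM, and the Iroquois factors Irx2, Irx3, Irx4 and Irx5 had log2 fold changes of -0.87, -1.14, -0.85 and -0.91. Among structural and neuronal markers, the synuclein gene Sncg (log2 fold change -1.07), the stathmins Stmn2 (-0.79) and Stmn3 (-1.04), the calcium-binding protein gene Calb2 (-1.22) and the neurofilament gene Nefl (-0.64) were lower, and Stmn2 went from 529 ± 54.0 to 306 ± 21.8 CPM. Eya2 (-0.76 ± 0.12) and Syt4 (-0.95 ± 0.15), the members with the smallest p of their lists, each had an edgeR adjusted p of 0.0513 over all genes.

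Of 25 tested ganglion cell transcription factors, 20 had a negative log2 fold change with a median of -0.38, and of 27 tested ganglion cell markers 24 were negative with a median of -0.60. Adjusted over the list alone, 10 of the transcription factors and 17 of the markers fell and none rose by edgeR. Over all genes none of either list was called by the genotype fit, and 10 and 15 fell with the batch term (12 and 20 adjusted over the list alone). Camera with a preset correlation placed both lists below other genes, with an adjusted p of 6.22e-07 for the transcription factors and 7.28e-11 for the markers. These became adjusted p = 0.326 and adjusted p = 0.318 with an estimated correlation. In fry, which asks whether a list moves one way, both had an adjusted p of 0.0594, or 0.0379 with the batch term. The mean log2 level of the markers was 6.24, 5.79 and 6.08 in WT 1, 2 and 3, and 5.56, 5.59 and 5.38 in REN_KO 1, 2 and 3. Relative to the WT mean the REN_KO libraries were at -0.47, -0.45 and -0.66, a comparison that crosses the sets of libraries. REN_KO 3, the lowest of its genotype, shares its set with WT 2, the lowest of WT.

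Axon guidance genes moved in both directions. Adjusted over the list alone, 6 of 39 tested genes rose and 5 fell by edgeR, 28 did not pass, and over all genes Robo3 was the sole call. The risers beside Robo3 were the ephrin receptor genes Epha3 (log2 fold change 0.63) and Epha5 (0.47), the plexin gene Plxna2 (0.63), Zic2 (0.55), a zinc finger factor of ganglion cells whose axons stay uncrossed, and Ncam1 (0.39). The genes that fell were the chemokine receptor gene Cxcr4 (-0.69), the growth cone gene Gap43 (-0.63), which also belongs to the marker list, the adhesion genes Chl1 (-1.35) and Cntnap2 (-0.38), and the netrin gene Ntn1 (-1.06). With the batch term 5 rose and 4 fell over all genes, and 6 rose and 7 fell adjusted over the list alone. The list's median was 0.05, between 0.00960 without REN_KO 3 and 0.09 without REN_KO 1 when libraries were left out. It was -0.00395 in the libraries with indexes 3 to 6, and -0.0508 after a trend on transcript length and GC content was removed. Fry gave an adjusted p of 0.0594, and 0.0919 with the batch term, and camera gave an adjusted p of 0.523 with the preset correlation and adjusted p = 0.649 with an estimated correlation.

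Some genes of neurogenic precursors and of other retinal neurons rose in REN_KO, none of them over all genes in the genotype fit. CPM are relative to the TMM-scaled library size, so a smaller share of ganglion cell RNA could still raise the values of lists from other cells. This was not tested. Adjusted over the list alone, edgeR called 7 of 24 neurogenic genes higher, among them the proneural factor genes Neurod1 (116 ± 17.6 CPM in WT, 217 ± 51.6 CPM in REN_KO, log2 fold change 0.90 ± 0.19), Neurog2 (0.54) and Neurod4 (0.59), and the zinc finger gene Insm1 (0.64). In the amacrine and horizontal cell list 5 of 22 rose on that basis, including Bhlhe22 (0.73 ± 0.16), Prox1 (0.82), a horizontal cell factor, and Gad2 (0.53), an enzyme of GABA synthesis. In the photoreceptor list 3 of 19 rose adjusted over the list alone, namely Neurod1, Rbp3 (0.74), which encodes the interphotoreceptor retinoid-binding protein, and Prdm1 (0.45). In the genotype fit no gene of the 3 lists fell on that basis, and 8, 6 and 3 of their genes rose over all genes with the batch term (12, 9 and 5 adjusted over the list alone). Rxrg, a retinoid X receptor gene of the photoreceptor list, had a log2 fold change of -0.59 with the batch term and fell there adjusted over the list alone (edgeR adjusted p = 0.0131). The medians were 0.35, 0.42 and 0.29, with camera adjusted p of 1.17e-06, 0.000359 and 0.00897 at the preset correlation. With an estimated correlation these were adjusted p = 0.318, adjusted p = 0.318 and adjusted p = 0.531. In fry the adjusted p was 0.0594, 0.0594 and 0.186, and 0.0379, 0.0379 and 0.237 with the batch term. The camera adjusted p of the photoreceptor list was 0.0864 without WT 2 and 0.0758 without REN_KO 1, its median was 0.15 without REN_KO 1 and 0.45 without REN_KO 2, and Neurod1 passed over all genes without REN_KO 3 (edgeR adjusted p = 0.0328).

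A minority of progenitor, Notch pathway and cell cycle genes rose adjusted over the list alone, and none over all genes in the genotype fit. The limit of relative levels given above holds for these lists too. Notch1 rose from 176 ± 5.58 to 276 ± 23.5 CPM (log2 fold change 0.65 ± 0.12) by the test adjusted over the list alone, as did Fzd5 (0.57) and Sfrp2 (0.69), a Wnt receptor and a secreted Wnt modulator of progenitors. On that basis 3 of 23 progenitor genes rose. So did 4 of 25 Notch pathway genes (Notch1, Notch3, Rbpj and Jag1) and 4 of 30 cell cycle genes (Cenpf, Mki67, Mcm4 and Cenpe). Cenpf, a kinetochore protein gene, had 252 ± 30.7 CPM in WT and 432 ± 43.5 CPM in REN_KO (0.78 ± 0.14). Negative values were found for 3, 4 and 9 members of the progenitor, Notch and cell cycle lists, and 3, 5 and 6 members rose over all genes with the batch term. Adjusted over the list alone with that term, 9, 8 and 8 rose, and the Notch ligand gene Jag2 (-0.64), the Notch-related Dner (-0.42) and the replication gene Gins2 (-0.42) fell (edgeR adjusted p = 0.0164, 0.0164 and 0.0320). The medians were 0.225, 0.262 and 0.20, and camera gave adjusted p of 0.00161, 0.000360 and 0.00390 at the preset correlation. With an estimated correlation these were adjusted p = 0.318, adjusted p = 0.335 and adjusted p = 0.318. In fry the adjusted p was 0.0594, 0.0728 and 0.0594, and 0.0919, 0.0919 and 0.0913 with the batch term.

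**Figure D2:**
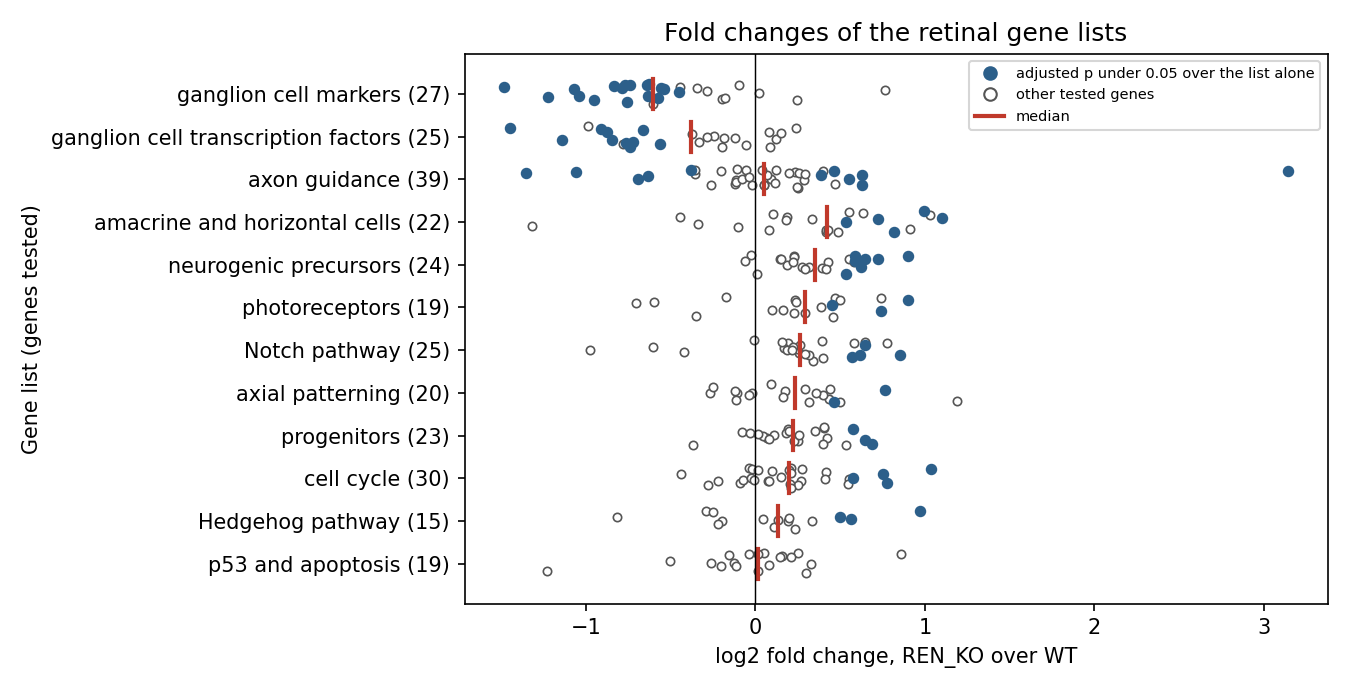
Log2 fold changes (REN_KO over WT) of every tested gene in the 12 retinal lists, with filled points for genes at an edgeR adjusted p under 0.05 over the list alone, open points for the other genes and a red line at each median. The medians of the 2 ganglion cell lists were -0.60 and -0.38, and that of the amacrine and horizontal cell list was 0.42.

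Of 15 Hedgehog pathway genes 3 rose adjusted over the list alone, the transcription factor genes Gli2 (log2 fold change 0.97) and Gli3 (0.57 ± 0.14) and the co-receptor gene Cdon (0.50), and the same number rose over all genes with the batch term. Shh, a ligand of the pathway, had a log2 fold change of -0.82 with that term and fell adjusted over the list alone (edgeR adjusted p = 0.0184, and 0.0796 in the genotype fit). Of 20 genes that pattern the retinal axes 2 rose adjusted over the list alone, Tbx3 (0.76 ± 0.18), a dorsal factor, and Epha5. Both rose over all genes with the batch term, where 4 rose adjusted over the list alone, and 6 genes of the axial list are also in the axon guidance list. None of 19 p53 and apoptosis genes passed on either basis in the genotype fit, where Sesn2, a stress-response gene, had a log2 fold change of 0.86 ± 0.26, and 1 gene, Sesn2, rose with the batch term. Camera adjusted p values at the preset correlation were 0.254, 0.108 and 0.749, and the corresponding values were adjusted p = 0.649, adjusted p = 0.577 and adjusted p = 0.817 with an estimated correlation. The axial list passed camera without WT 2 (adjusted p = 0.0104) and without REN_KO 1 (adjusted p = 0.0149). The p53 list had a median of 0.02 (-0.02 without WT 2), a mean of -0.01 and a camera direction of up.

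Lens genes differed among libraries more than between genotypes. Cryaa, which encodes alpha-crystallin, had 63.9, 4.43 and 14.4 CPM in WT 1, 2 and 3, and 167, 925 and 6.21 CPM in REN_KO 1, 2 and 3, and the lens list took from 0.00209% of gene reads in WT 2 to 0.279% in REN_KO 2. The mean log2 CPM of the lens list was higher in REN_KO within both sets of libraries, at 4.26 and 6.30 in REN_KO 1 and 2 against 3.33 and 1.86 in WT 1 and 3, and at 0.41 in REN_KO 3 against -0.27 in WT 2. The median log2 fold change of 18 lens genes was 2.80, or 1.05 without REN_KO 2 and 3.91 without WT 1, the largest being that of Cryaa at 3.72 ± 1.36, and Gja8, a lens connexin gene, had 3.46 ± 1.05. No lens gene was called by the genotype fit over all genes or adjusted over the list alone, 14 were called higher over all genes with the batch term and 18 adjusted over the list alone, and camera gave an adjusted p of 0.00216 and adjusted p = 0.649 with an estimated correlation. The camera adjusted p was 0.117 without WT 2 and 0.232 without REN_KO 2, and Gja8 passed over all genes without REN_KO 3 (edgeR adjusted p = 0.0328). Without the lens, blood and pigment epithelium genes and the mitochondrial transcripts, the genotype fit called 11 genes higher and 24 lower.

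The remaining lists of other tissues and of handling showed few calls, apart from the sex-linked list. Over all genes the genotype fit called none of their members. Adjusted over the list alone in the same fit, the endothelial receptor gene Kdr rose (147 ± 13.8 CPM in WT, 225 ± 5.02 CPM in REN_KO) as 1 of 16 vascular genes, and Hbb-bh1, an embryonic globin gene, fell (log2 fold change -3.12 ± 0.86, from 1.60 to 0.186 CPM) as 1 of 7 erythroid genes, where the more abundant Hbb-y had -0.84 ± 0.44. Of 5 sex-linked genes, the Y-linked Ddx3y (0.80 ± 0.19) and Kdm5d (0.47) rose and the X-inactivation transcript Xist (-0.69 ± 0.25) fell on that basis. In that fit no gene passed adjusted over the list alone among 13 ciliary margin genes (Zic2, 0.55 ± 0.15), 15 pigment epithelium genes (Trpm1, -0.10 ± 0.22, and Pmel, -0.20 ± 0.15) or 13 mesenchyme genes (Fbn1, 0.59 ± 0.17). The same held for 15 microglia genes (Ctss, 0.13 ± 0.21, and Csf1r, 0.57 ± 0.19), 7 optic stalk and astroglial genes (Slc1a3, 0.06 ± 0.14, and Pax2, -1.60 ± 0.61), 13 immediate early genes (Jun, 0.26 ± 0.13, and Arc, 1.20 ± 0.54) and 16 hypoxia and glycolysis genes (Ldha, -0.53 ± 0.15). With the batch term Kdr, Ddx3y, Zic2 and Fbn1 rose and Ldha fell over all genes, and no other member of these lists was called over all genes. On the basis of the list alone with that term, edgeR also called the microglial gene P2ry12 (log2 fold change 0.74), the pericyte gene Pdgfrb (0.61) and the Y-linked Uty (0.36) and Eif2s3y (0.33) higher and the hypoxia genes Pdk1 (-0.47) and Bnip3 (-0.59) lower, and the calls on Hbb-bh1, Xist and Kdm5d remained. All 5 sex-linked genes thus passed there, 4 higher and 1 lower. The sex of the embryos is not given in the sources used here. For these genes, sex makeup cannot be told apart from genotype.

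None of these 10 lists passed camera with all 6 libraries when no trend on transcript length and GC content was removed. The adjusted p at the preset correlation was 0.643 for the vascular list, 0.208 for the erythroid, 0.172 for the sex-linked, 0.389 for the ciliary margin, 0.902 for the pigment epithelium, 0.497 for the mesenchyme, 0.497 for the microglia, 0.490 for the optic stalk, 0.0950 for the immediate early and 0.330 for the hypoxia list, and the values ran from adjusted p = 0.326 to adjusted p = 0.948 with an estimated correlation. Camera passed the erythroid list without WT 1 (adjusted p = 0.0102), the vascular list without WT 3 (0.0344), the mesenchyme list without WT 2 (0.00900), the immediate early list without REN_KO 2 (0.0332) and the hypoxia list without REN_KO 3 (0.0372). After that trend was removed with all 6 libraries, the mesenchyme list alone of the 10 passed (median -0.732, camera adjusted p = 0.0401). That test was the pre-ranked form of camera, run on the remaining log2 fold changes over their SE at the preset correlation alone. The estimated correlation of the mesenchyme list was 0.47. With it, camera gave an adjusted p of 0.823 before the trend was removed. In the vascular and pigment epithelium lists the median (-0.08 and -0.03) and mean (-0.06 and -0.05) were negative while camera's direction was up. The vascular median turned positive without WT 3 (0.35), REN_KO 1 (0.18) or REN_KO 2 (0.05), and the pigment epithelium median did so without WT 3 (0.175) or REN_KO 1 (0.000743).

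Genes near Atoh7 on chromosome 10 were not called by the genotype fit. Of 16 tested neighbours, Tet1, which encodes a 5-methylcytosine dioxygenase, had the smallest p, with a log2 fold change of 0.49 ± 0.16 (edgeR adjusted p = 0.208), and it rose with the batch term (edgeR adjusted p = 0.0360). In the genotype fit none of the neighbours passed adjusted over the list alone, and on that basis Tet1 and Ccar1 (log2 fold change 0.44, a coactivator gene) rose with the batch term (edgeR adjusted p = 0.0190 and 0.0308). Their mean was -0.04 and their median 0.09, or 0.03 without WT 2, 0.00187 without REN_KO 2 and 0.02 without REN_KO 3. The camera direction was up, with an adjusted p of 0.497 and adjusted p = 0.649 with an estimated correlation, and fry, also up, gave an adjusted p of 0.0728, and 0.0379 with the batch term. Atoh7 itself was the 1 called gene among 702 tested on chromosome 10, against 11 of 13858 with a position on other chromosomes (Fisher's exact test, two-sided, p = 0.447). Under the batch term the counts were 36 of 702 and 716 of 13858 (p = 1, Fisher's exact test).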

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

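In the pattern weighed here, the batch test, the test of other retinal lists and the test of a lower ganglion cell share, and the splits for the gene counts of the genotype fit, were chosen after the results were seen.

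Reads on the strand opposite to Slc7a11 (chromosome 3, 49892526 to 50443614, minus strand), a cystine transporter gene, were seen in the count column that the comparisons left out. They numbered 142, 8 and 37 in WT 1, 2 and 3, and 1105, 1901 and 3478 in REN_KO 1, 2 and 3, and made up 78.2% of the strand-specific reads of the gene. In an edgeR fit of that column with the batch term the log2 fold change was 5.17, with an edgeR adjusted p of 0.0218, the 1 call of that fit. Without the batch term edgeR called none of 4576 genes tested in that column, with 68 at an unadjusted p under 0.05, and the adjusted p of Slc7a11 was 1. Slc7a11 itself had a log2 fold change of 1.20 on the transcribed strand (edgeR adjusted p = 0.0513, and 0.00589 with the batch term). The gene was chosen after its values were seen, and no source for the opposite reads was tested.

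The 2 ganglion cell lists had negative medians in REN_KO. The values below argue against each of these as the whole of it: a difference between library sets, a trend on transcript length and GC content, and dilution by other tissue. A shift shared by a set of libraries would cancel, since both sets hold the genotypes in equal number. The difference was not confined to 1 set either. The median log2 fold change of the markers was -0.483 (SE 0.0525) within indexes 11 and 12, 1 library per genotype. Within the other set it was -0.665 (SE 0.101). Each SE in this paragraph comes from resampling the genes of a list and holds no spread between libraries. After the trend on transcript length and GC content was removed, the median of the markers was -0.529 (SE 0.0779). That of the ganglion cell transcription factors was then -0.477 (SE 0.157). Dilution of the retina by tissue of other kinds would lower other retinal genes too, yet the lowest median of the progenitor, neurogenic, photoreceptor and amacrine and horizontal cell lists was 0.225 (SE 0.0727). A lower share of ganglion cells and lower expression of these genes per cell both stay open, since bulk RNA does not separate the 2 and the 88.9% of markers with a negative value are the pattern itself.

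The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. For genes higher and for genes lower 1 of 10 splits, the real one, gave as many, with 6 and 7 genes against a highest other value of 0. For the camera p of the marker list 1 of 10 was as small (3.03e-12, with 1.17e-06 as the lowest other), for the transcription factor list 1 of 10 (5.19e-08, with 0.000345) and for the axon guidance list 3 of 10 (0.458, with 0.322). With the batch term 6 splits are possible, also too few, and 1 of 6 gave as many genes higher (479, highest other 0) and 1 of 6 as many lower (276, highest other 0).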

How the results depend on the processing

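The added settings, chosen after seeing the data, were edgeR's robust moderation, DESeq2 with the batch term and the counts of the batch-term fit. Genes higher and lower in REN_KO, 6 and 7 by edgeR on genotype, were 6 and 7 with RLE size factors, 9 and 7 in the unstranded column, 12 and 27 with library-size scaling, 262 and 161 with DESeq2, and 2 and 3 with limma voom. They were 179 and 122 with no low-count filter, 10 and 31 with a filter of 5 CPM in 3 libraries, and 479 and 276 with the batch term. They were 119 and 83 in the libraries with indexes 3 to 6, 11 and 24 without lens, blood and pigment epithelium genes, and 11 and 30 with robust moderation. They were 891 and 481 with DESeq2 and the batch term (also the DESeq2 value of the batch-term count), and 1 and 0 at an adjusted p under 0.01, where edgeR had 2157 genes at an unadjusted p under 0.05. With a replicate block they were 3 and 1. The replicate numbers do not pair the libraries, since deviations from the group means correlated at 0.149, -0.228 and -0.129 between equal numbers. Without each library in turn they ranged from 1 (without WT 3) to 13 (without REN_KO 3) and from 0 (without WT 3) to 24 (without WT 2). With the batch term they ranged from 11 (without REN_KO 2) to 294 (without WT 3) and from 13 (without REN_KO 2) to 257 (without WT 3). For the changed counts the cause was not tested. The share of called genes that were higher was 46.2% in the genotype fit, 30.8% with library-size scaling, 24.4% with the stricter filter, 59.5% with no filter, 61.9% with DESeq2 and 63.4% with the batch term. Atoh7 stayed negative in every setting, from -2.97 (without REN_KO 3) to -2.35 (without WT 2) when libraries were left out, with adjusted p from 3.93e-90 in DESeq2 with the batch term to 0.136 in edgeR without REN_KO 2. Camera placed both ganglion cell lists lower in every setting, with an adjusted p of 0.326 (transcription factors) and 0.318 (markers) with an estimated correlation and 0.0594 for both with fry. The cause was not tested. For the 40 named genes 604 of 751 values kept direction and side of the threshold, and for the 24 set tests 445 of 498 did. Direction reversed, and the cause was not tested, for Ctss in the libraries with indexes 3 to 6 (log2 fold change -0.14). With libraries left out it reversed for Ctss (-0.0114 without REN_KO 3 to 0.37 without WT 3), Trpm1 (-0.29 without WT 1 to 0.13 without WT 3) and Slc1a3 (-0.00446 without WT 2 to 0.15), none of which passed. Camera's direction reversed for the pigment epithelium list with voom (adjusted p = 0.845), the stricter filter (0.931) and indexes 3 to 6 (0.617), for the vascular list with indexes 3 to 6 (0.840). It also reversed in at least 1 fit without a library for 7 lists. The adjusted p ranges given next cover every fit without a library, reversed or not. They were 0.284 to 0.948 (pigment epithelium), 0.0344 to 0.756 (vascular), 0.640 to 0.939 (p53) and 0.0563 to 0.945 (ciliary margin). For the others they were 0.116 to 0.996 (microglia), 0.126 to 0.939 (optic stalk) and 0.526 to 0.956 (neighbours of Atoh7). None of the reversed fits passed. The vascular list reversed without WT 1 (adjusted p = 0.293) and without REN_KO 3 (0.756). Its 0.0344, without WT 3, came from a fit that kept the direction. In simulated libraries of the same depth the genotype fit called 4.08% of 1.5-fold changes and the fit with the batch term 38.8%. A batch difference was built into that simulation and genes were drawn independently, so the shares may differ in the real libraries.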

Other observations

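The genes and families named in this part, the tests on the RNase P RNA-like genes, the test on genes outside the retinal lists and the comparison of length slopes within each set of libraries were chosen after the results were seen.

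None of the genes in this paragraph but Rian and Peg3 was called by the genotype fit, and no list of tubulin or imprinted genes was tested. Tuba1c rose with the batch term from a mean of 59.6 ± 14.7 to 224 ± 88.6 CPM (log2 fold change 1.87, edgeR adjusted p = 9.7e-06, and 0.0513 without the term), while the neuronal alpha-tubulin gene Tuba1a fell with it (-0.81, edgeR adjusted p = 0.00140), as did Tuba1b (-0.85) and Tubb2a (-0.79). Meg3, from the same maternally expressed cluster as Rian, fell with the batch term (-1.11, edgeR adjusted p = 0.00983), as Rian did (-0.92), while the paternally expressed Peg3 rose (0.92). Others that fell with the batch term were Islr2 (-1.04, edgeR adjusted p = 0.00385), an immunoglobulin-superfamily gene of axons, Lmo2 (-1.29, 0.000714), a LIM-domain factor, P2rx3 (-1.61, 0.00105), an ATP-gated channel gene, and Car10 (-1.70, 0.00319). Pik3r1, a regulatory subunit of phosphoinositide 3-kinase, rose (1.05, 0.00337).

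The Rprl genes had more reads in every REN_KO library than in any WT library. Rprl2 had 113, 2 and 9 reads in WT 1, 2 and 3 and 2854, 1869 and 1950 in REN_KO 1, 2 and 3. Reads shared with Rpph1 at a fixed rate would keep the ratio of Rprl to Rpph1 reads alike. The lowest REN_KO ratio was instead 18.0 times the highest WT ratio. The ratio was not alike within WT either, where WT 2 had the most Rpph1 reads (716169) and the fewest Rprl2 reads. A rate of sharing that differs between libraries was therefore not excluded. The smallest rise of the 3 genes in either set of libraries was 22.3 fold, so the rise was not confined to 1 set. A shift shared by a set would cancel, since both sets hold the genotypes in equal number. Rprl2 and Rprl3, the 2 with a single annotated position, lie on chromosomes 3 and 8, off the chromosome of the targeted Atoh7 locus. A background difference between the lines that is not linked to Atoh7 could also raise them and stays open, since 0 of the files hold genotypes.

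Longer transcripts were higher in REN_KO relative to shorter ones, with a rank correlation of 0.42 between log2 fold change and transcript length over 11073 genes at 5 CPM or more. The correlation was 0.369 in the lower of the 2 sets of libraries, so it was not confined to 1 set. A shift shared by a set would cancel between the genotypes. Among 10181 genes outside the retinal lists and the calls the correlation was 0.398, against those genes as its source. Selection on RNA length that varies between libraries cannot be told apart from a genotype effect: the mean slopes differed by 2.02 times the larger range within a genotype, short of the 3 set for the test, and by 3.95 times (difference 0.117) among the libraries with indexes 3 to 6, where that range comes from 2 libraries per genotype. The pair with indexes 11 and 12 differed by 0.104, with 1 library each. No biological explanation was tested.

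Ribosomal protein genes, which are short, had negative log2 fold changes in 45 of 45 Rpl and 36 of 46 Rps genes, with camera adjusted p over 175 families (10 or more tested genes that share a symbol stem) of 5.11e-06 and 0.00695, and adjusted p = 0.590 for each with an estimated correlation. Their medians of -0.27 and -0.21 were -0.04 and -0.00927 after the trend on length and GC was removed.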
